A study of Homo sapiens with 2 samples.

How the data were processed

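RNA was measured in MCF-7 cells, an estrogen receptor-positive luminal breast adenocarcinoma line. One culture stably expressed a scrambled short hairpin RNA (shCtrl) and the other a hairpin against EXOSC3 (shEXOSC3), which encodes a core subunit of the RNA exosome, the 3'-to-5' exonuclease complex of nucleus and cytoplasm. Per the labels' protocols, total RNA from growing cells was purified on RNeasy columns and treated with DNase, and libraries were made with the KAPA RNA HyperPrep kit with RiboErase, which removes cytosolic and mitochondrial ribosomal RNA. Transcripts without a poly(A) tail are therefore kept. There was 1 library per group.

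Per the submitters' processing notes, STAR and Cuffdiff were used with the human build hg38. Their versions and settings, the annotation, and whether reads were counted by strand are not given in the sources used here. The deposited table has 60468 rows, each a gene identifier and symbol, with 1 value per group. These values are taken as FPKM as the authors' Cuffdiff run would give them (fragments per kilobase of transcript, relative to the library size), because the deposited header names no unit. The authors' p-value and log2 fold change stand beside them in the deposited table. The authors' log2 fold change equals log2((shEXOSC3 + 0.1)/(shCtrl + 0.1)). The deposited table has no adjusted p, so the comparison with the authors' q values was not run. Whether more than 1 library was pooled into either column is not stated.

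The authors' table marks 20208 rows as tested, 40155 as too low for a test, 63 as HIDATA (Cuffdiff's word for a locus with too many fragments) and 42 as FAIL. Of the HIDATA rows, 57 are listed at 0 in both libraries, among them KRT8, KRT18 and RN7SK, so these zeros were read as failed estimates. HIDATA and FAIL rows were left out of all comparisons except the setting that keeps failed estimates, a choice made after seeing the data. They stayed in the sums of FPKM behind the scaling to equal sums and behind the mitochondrial share of all FPKM. Gene positions, classes, transcript lengths and GC content came from GENCODE release 29 (hg38), which held 56746 of the 60468 identifiers. Length and GC content are those of the longest annotated transcript.

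Depth was estimated from low values. In genes with 1 annotated transcript and no test by the authors, FPKM was multiplied by length less a fitted offset. The offset was 162 bp for shEXOSC3 and 158 bp for shCtrl. The product was a whole multiple of 1 fragment, within 0.1, for 97.0% of 2228 genes in shEXOSC3 and 97.3% of 1954 in shCtrl. Offset and depth were chosen to make this share largest, whereas the chance share of 20% is for 1 fixed setting. The fitted depths were 94700000 fragments for shEXOSC3 and 91700000 for shCtrl, on the authors' scale. At 1 FPKM a transcript of 2 kb then rests on 174 and 169 fragments, a 95% counting interval of about ±15%, which covers counting error only.

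With 1 library per group no test was made between groups and no p-value was computed. The difference is given as log2((shEXOSC3 + 0.5)/(shCtrl + 0.5)), called the log2 ratio, on the authors' scaling. It understates the change of low genes. Features with a mean over both libraries of at least 1 FPKM and a genomic span of at least 300 bp, or no span in the annotation, were counted as higher at a log2 ratio of at least 1 and as lower at -1 or below. Shorter features were counted apart. There were 36 gene lists. For each list with at least 5 members, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test, since genes of a list are not independent. Lists at or above percentile 97.5 or at or under 2.5 are said to stand apart. Groups, lists, rule of size, alternatives and the rule for named genes were fixed before the data were examined. That rule takes EXOSC3, the 12 features with the highest and the 12 with the lowest log2 ratio, the exosome subunits, and of each list described the 2 to 4 members with the largest absolute log2 ratio.

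A second percentile was added after seeing the data. For it, a quadratic trend of the log2 ratio on transcript length and GC content, fitted on 10246 nuclear protein-coding genes outside the lists (zinc finger genes kept), was subtracted from each gene. The other settings fixed beforehand were pseudocounts of 0.1 and 1, no filter and a mean of at least 5 FPKM, 3 other scalings, short features kept, rows with 1 symbol summed, and protein-coding genes only. Those added after seeing the data were failed estimates kept, the length and GC trend removed, features listed at 0 left out, mitochondrial genes left out, and the authors' p under 0.05 in place of the rule of size.

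The scripts were tested on simulated data built from these libraries. Over 12738 genes, the rule of size recovered 94.0% of genes simulated at a log2 change of 2, 91.7% at -2, 100.0% at 3 and 100.0% at -3. It took 2.88% of unchanged genes over both directions. Of unchanged lists of 30 genes, 4.0% fell outside percentiles 2.5 to 97.5, and 100.0% of lists raised by 0.5 were found. Noise was drawn independently per gene, with its size taken from the quartile range of the real log2 ratios. The simulation held no length, GC or level trend, and its rates do not cover lists whose genes move together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.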

Results

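Total RNA depleted of ribosomal RNA was sequenced from MCF-7 breast adenocarcinoma cells that stably expressed either a scrambled hairpin (shCtrl) or a hairpin against EXOSC3 (shEXOSC3). Each group had 1 library, with a fitted depth of 94700000 fragments for shEXOSC3 and 91700000 for shCtrl. Levels are the authors' FPKM, and differences are log2 ratios of shEXOSC3 over shCtrl with a pseudocount of 0.5 FPKM. Because no group was replicated, every difference is one between 2 libraries with no replicate check, and none has an error across cultures. The comparison addresses which transcripts differ in level when the RNA exosome subunit EXOSC3 is depleted.

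EXOSC3 (ENSG00000107371, hg38 chromosome 9, 37766978 to 37801437, minus strand) was at 57.1 FPKM in shCtrl and 6.15 FPKM in shEXOSC3, 9.28-fold lower, in the direction of its label. Of 13 mitochondrially encoded mRNAs 12 were at least 2-fold higher in the knockdown library, as were 9 of 29 immediate early genes and 9 of 35 estrogen-induced genes. The nuclear long non-coding RNAs MALAT1 and NEAT1 were also at least 2-fold higher, but their list of 15 did not stand apart (median -0.005). Of 62 replication-dependent histone genes 35 were at least 2-fold lower. G2/M genes (median log2 ratio -0.79) and G1/S genes (-0.62) lay below random lists matched on expression, with 3 of 33 and 0 of 43 past 2-fold. Of 12894 features with a mean of at least 1 FPKM, 628 (4.87%) were at least 2-fold higher in shEXOSC3 and 155 (1.2%) at least 2-fold lower. In simulated data the rule of size took 2.88% of unchanged genes over both directions. The noise there was sized from these same log2 ratios, so this rate cannot show whether either count is in excess. The median log2 ratio of all features was -0.05, with quartiles of -0.34 and 0.30. The count of higher features was 319 at a mean of at least 5 FPKM, and that of lower features was 98 with both libraries scaled to equal upper quartiles.

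Among the 12 features with the highest log2 ratio, 6 with no position in the annotation were listed at 0 in shCtrl and at up to 38.9 FPKM in shEXOSC3 (AC100800.2). The others were MT-RNR1, the nuclear copy of a mitochondrial gene MTATP6P1, MT-CYB, MT-ATP6, MT-ND4 and BCL9L. BCL9L, a coactivator of beta-catenin, was at 4.96 FPKM in shCtrl and 45.3 FPKM in shEXOSC3, a log2 ratio of 3.07. Features listed at 0 in shEXOSC3, again without a position, made up 9 of the 12 lowest, and the other 3 were EXOSC3, FCGRT and HSD17B6. FCGRT, the heavy chain of the neonatal Fc receptor, was at 4.48 FPKM in shCtrl and 0.579 FPKM in shEXOSC3, a log2 ratio of -2.20. HSD17B6, a hydroxysteroid dehydrogenase, was at 5.67 and 1.16 FPKM, a log2 ratio of -1.90.

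Because of the features listed at 0, further genes above 0 in both libraries were named after their values were seen. On the higher side these were MSMB at a log2 ratio of 3.03, the transcriptional corepressor CBFA2T3 at 2.86 and the transcriptional coregulator ZMIZ1 at 2.61. On the lower side they were SLC25A48 at -1.89, C3orf14 at -1.82, the heparan sulfate endosulfatase SULF1 at -1.64, the glycosyltransferase B3GNT2 at -1.53 and the lectin CLEC3A at -1.52.

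**Figure D1:**
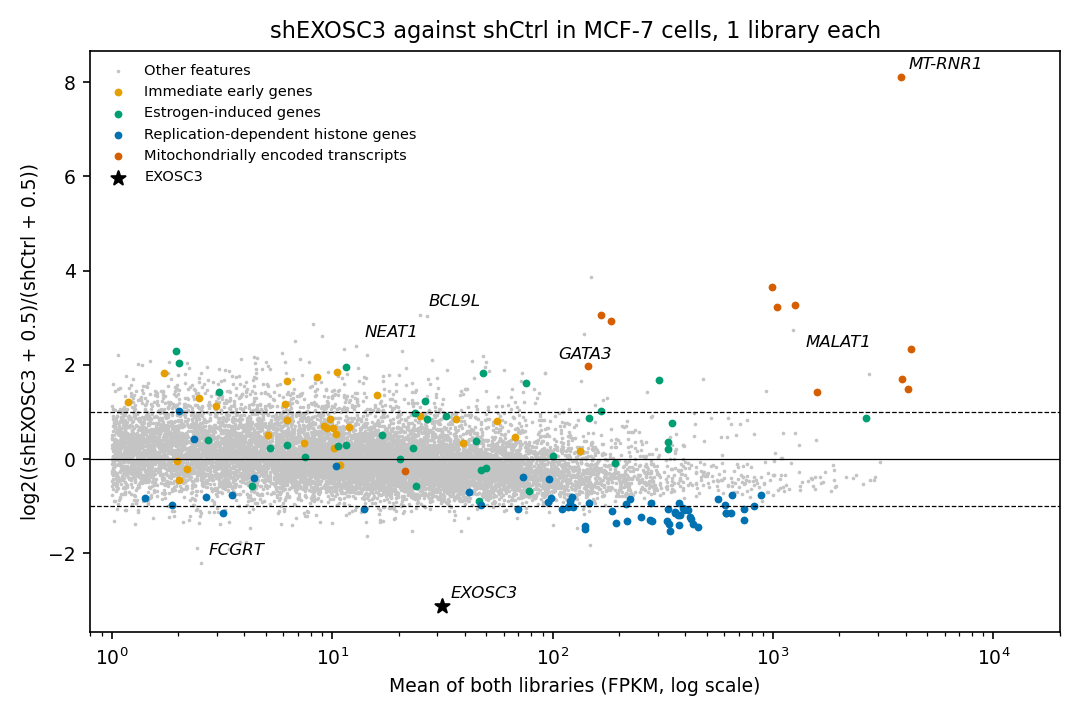
Each point is 1 feature above 0 in both libraries and not under 300 bp, with its mean over both libraries on the x axis (FPKM, log scale) and its log2 ratio of shEXOSC3 over shCtrl (pseudocount 0.5) on the y axis; dashed lines mark 2-fold, and colours mark 4 gene lists and EXOSC3. EXOSC3 is the lowest point at -3.11, mitochondrial transcripts reach 8.11 with MT-RNR1, and 35 of 62 histone genes lie at or below the lower 2-fold line.

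The other subunits of the exosome were also lower, though none by 2-fold. All 10 measured members, the catalytic ribonucleases DIS3, DIS3L and EXOSC10 among them, had a negative log2 ratio, with a median of -0.47 at percentile 0.82 of random lists matched on expression. EXOSC8 was at 51.9 FPKM in shCtrl and 28.2 FPKM in shEXOSC3, EXOSC5 at 24.9 and 13.9 FPKM, and EXOSC2 at 57.0 and 33.8 FPKM. The log2 ratios of the others were -0.64 for EXOSC7, -0.50 for EXOSC4, -0.45 for DIS3L, -0.36 for EXOSC1, -0.35 for EXOSC10, -0.30 for DIS3 and -0.13 for EXOSC6. With the trend on transcript length and GC content removed, the percentile was 2.51, just inside the bound of 2.5. Exosome cofactors did not stand apart, with a median of -0.14 at percentile 38.77 over 25 members, of which ZC3H3 (log2 ratio 1.02) and ZFC3H1 (1.01) were over 2-fold higher. Both proteins belong to the route that targets polyadenylated nuclear RNA to the exosome. RNA decay factors outside the exosome had a median of 0.12 at percentile 99.21, with 2 of 34 at least 2-fold higher, and 0.05 at a mean of at least 5 FPKM. The 2 higher members were the CCR4-NOT subunit CNOT3, at 6.34 FPKM in shCtrl and 22.1 FPKM in shEXOSC3, a log2 ratio of 1.72, and the nonsense-mediated decay factor SMG7, at a log2 ratio of 1.03.

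LINC and antisense transcripts stood apart as higher among the lists of long non-coding RNAs. LINC transcripts had a median log2 ratio of 0.30 at percentile 99.74, with 9 of 88 at least 2-fold higher and 0 lower, led by LINC01588 (1.87) and LINC01468 (1.68). Random lists had 0.11, and with no filter on low values the median was 0.04 over 379 transcripts. Transcripts named as antisense had a median of 0.21 at percentile 99.73, with 18 of 253 at least 2-fold higher and 0 lower, led by SEPSECS-AS1 (1.92) and PDCD4-AS1 (1.54). Random lists had 0.11, and with no filter the median was 0.09 over 615 transcripts. The percentiles rank medians, and the counts past 2-fold were not ranked against random lists. Among all features, 107 of 1290 in the lowest decile by mean FPKM and 124 of 1289 in the next were at least 2-fold higher. The LINC and antisense counts alone therefore show no clear excess. Antisense values are uncertain because it is not stated that reads were counted by strand. Across 382 pairs of an antisense gene and the protein-coding gene it overlaps, the log2 ratios had a Spearman rho of 0.06, across genes that are not independent replicates, and the antisense gene had the higher ratio in 267 pairs. Of 15 well-studied nuclear long non-coding RNAs, 3 were at least 2-fold higher, and the list's median of -0.01 at percentile 72.41 did not stand apart. MALAT1, a nuclear speckle RNA, was at 323 FPKM in shCtrl and 2151 FPKM in shEXOSC3, NEAT1, the scaffold of paraspeckles, at 3.73 and 21.9 FPKM, and HOTAIRM1 at 2.51 and 6.27 FPKM.

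Small nucleolar RNAs went both ways, with 36 of 143 at least 2-fold higher, 26 at least 2-fold lower and a median of -0.02 at percentile 96.21. Of these, 23 of the higher were listed at 0 in shCtrl and 15 of the lower at 0 in shEXOSC3, so that 13 and 11 of the 105 members above 0 in both libraries were past 2-fold. SNORD12C and SNORA67 were listed at 0 in shCtrl and at 168 and 52.4 FPKM in shEXOSC3, and SNORD118 was at 57.9 FPKM in shCtrl and listed at 0 in shEXOSC3. Their long non-coding host genes had a median of -0.14 at percentile 60.38 over 24 members, with SNHG9 at 73.4 FPKM in shCtrl and 148 FPKM in shEXOSC3, SNHG15 at 17.6 and 10.1 FPKM, and SNHG6 at 126 and 78.9 FPKM. Small nuclear and other structural RNAs had a median of 0.48 at percentile 100, with 6 of 30 at least 2-fold higher and 3 lower. RNVU1-14 was at 29.8 FPKM in shCtrl and 0.033 FPKM in shEXOSC3, RNU1-4 was listed at 0 in shCtrl and at 2.29 FPKM in shEXOSC3, RNVU1-18 was at 4.83 and 0.762 FPKM, and RNU1-1 was at 0.806 and 3.81 FPKM. Most of these RNAs are short, and many have near-identical copies, so their values are uncertain. Among 358 features under 300 bp, 104 were at least 2-fold higher and 63 lower, and 94 were listed at 0 in 1 library. MicroRNA host genes had a median of 0.37 at percentile 89.27 over 8 members, with MIRLET7BHG at 0.88 and MIR17HG at -0.75.

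Mitochondrially encoded mRNAs had a median log2 ratio of 2.59, 6.01-fold, and 12 of the 13 were at least 2-fold higher. They took 4.44% of all FPKM in shEXOSC3 and 1.05% in shCtrl. These totals include failed estimates, among them RNaseP_nuc at 57318.6 FPKM in shEXOSC3 and at 0 in shCtrl. MT-CYB was at 146 FPKM in shCtrl and 1841 FPKM in shEXOSC3, MT-ATP6 at 235 and 2285 FPKM, and MT-ND4 at 198 and 1877 FPKM. MT-ND6, the 1 mRNA encoded on the other strand, which was named after its value was seen, was at 23.3 FPKM in shCtrl and 19.5 FPKM in shEXOSC3. MT-RNR1, the small mitochondrial ribosomal RNA that library preparation depletes, was at 27.0 and 7561 FPKM. Of the list as fixed, 12 members span at least 300 bp, with a median of 2.64 at percentile 100. Without genes of the mitochondrial chromosome, 617 features were at least 2-fold higher and 155 lower. The nuclear copy MTATP6P1, at 18.7 FPKM in shCtrl and 280 FPKM in shEXOSC3, stays in this count. Whether its value comes from reads of MT-ATP6 was not tested.

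Replication-dependent histone mRNAs, which end in a stem-loop and lack a poly(A) tail, had a median log2 ratio of -1.05, 2.07-fold lower, at percentile 0. Of 62 members 35 were at least 2-fold lower and 1 was at least 2-fold higher, HIST2H2BC, which was named after its value was seen. The members were taken by symbol, and the 60 annotated as protein-coding had a median of -1.052. HIST1H1D was at 505 FPKM in shCtrl and 174 FPKM in shEXOSC3, HIST1H4F at 208 and 74.0 FPKM, and HIST1H1B at 668 and 247 FPKM. Reads may be shared among copies of near-identical sequence, which leaves single members uncertain. Polyadenylated histone variants had a median of -0.23 at percentile 63.39 over 11 members, with H2AFZ at -0.79 and CENPA at -0.68.

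Genes of the cell cycle were lower alongside the histones. G2/M genes had a median of -0.79 at percentile 0, with 31 of 33 below 0 and 3 at least 2-fold lower. These were the mitotic kinesin KIF20A, at 82.6 FPKM in shCtrl and 38.1 FPKM in shEXOSC3, the chromosomal passenger protein BIRC5, at 83.9 and 39.3 FPKM, and the spindle protein HMMR, at 72.4 and 35.4 FPKM. G1/S and DNA replication genes had a median of -0.62 at percentile 0, with 40 of 43 below 0 and 0 past 2-fold, led by CCNE2 (-0.97), E2F1 (-0.93) and ORC1 (-0.93). DNA repair genes had a median of -0.36 at percentile 0.06, with 35 of 38 below 0 and the helicase BLM (-1.04) over 2-fold lower, whereas the topoisomerase TOP1 was at 0.83.

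Gene lists of hormone response, luminal identity and basal or mesenchymal state had positive medians. Estrogen-induced genes had a median of 0.38 at percentile 100, with 9 of 35 at least 2-fold higher and 0 lower. KRT13 was at 0.324 FPKM in shCtrl and 3.58 FPKM in shEXOSC3, the progesterone receptor PGR at 0.483 and 3.53 FPKM, the cadherin CELSR2 at 4.43 and 18.6 FPKM, and the retinoic acid receptor RARA at 21.1 and 76.1 FPKM. The luminal list had a median of 0.37 at percentile 99.99, with 2 of 21 members at least 2-fold higher. The luminal transcription factor GATA3 was at 37.6 FPKM in shCtrl and 239 FPKM in shEXOSC3, AGR3 was at 0.22 and 2.40 FPKM, TFAP2A was at 4.13 and 8.59 FPKM, and SPDEF was lower at 106 and 59.5 FPKM. Mesenchymal and basal genes also had a positive median, 0.54 at percentile 99.57, with 2 of 13 members at least 2-fold higher, and 0.12 over 28 members with no filter on low values. Integrin ITGB4 was at 10.4 FPKM in shCtrl and 46.4 FPKM in shEXOSC3, TP63 was at 0.322 and 2.17 FPKM, and TGFBI was lower at 5.57 and 2.61 FPKM.

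Targets of TP53 had a median of 0.44 at percentile 100, with 28 of 33 above 0, 5 at least 2-fold higher and 0 lower. SPATA18 was at 0.915 FPKM in shCtrl and 3.60 FPKM in shEXOSC3, the cyclin-dependent kinase inhibitor CDKN1A at 42.8 and 122 FPKM, and the antiproliferative gene BTG2 at 8.71 and 23.1 FPKM. Immediate early genes, whose mRNAs turn over fast, had a median of 0.71 at percentile 100, with 9 of 29 at least 2-fold higher and 0 lower. ZFP36, which binds AU-rich elements in mRNA, was at 4.27 FPKM in shCtrl and 16.7 FPKM in shEXOSC3, EGR1 at 0.485 and 2.98 FPKM, ZFP36L1 at 3.67 and 13.4 FPKM, and FOS at 2.71 and 9.70 FPKM.

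Genes of translation and nuclear-encoded genes of respiration were lower by small amounts across most members. Ribosomal proteins had a median of -0.48 at percentile 0.15, with 79 of 82 below 0, and random lists of the same expression had -0.35. RPL22L1 was at 189 FPKM in shCtrl and 68.4 FPKM in shEXOSC3, RPL39L was at 81.7 and 43.6 FPKM, and RPL28 and RPS16 had log2 ratios of 0.98 and 0.87. Ribosome biogenesis factors had a median of -0.38 at percentile 0.13 over 45 members, against -0.18 in random lists, and 2 were at least 2-fold lower, the nucleolar RNA helicase DDX21, at 146 and 55.5 FPKM, and MRTO4, at 46.6 and 22.9 FPKM. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.45 at percentile 0.03, with 68 of 75 below 0 and 0 past 2-fold, led by SDHD (-0.94) and NDUFA9 (-0.82), and random lists of the same expression had -0.30. Genes of the integrated stress and unfolded protein responses had a median of -0.38 at percentile 0.11 over 35 members, with VLDLR at 1.33 and NUPR1 at -1.11. Interferon-stimulated genes had a median of -0.25 at percentile 0.9, with 24 of 31 below 0, led by PSMB9 (-1.08) and IFIT1 (-0.96), and the median was -0.09 over 18 members at a mean of at least 5 FPKM.

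**Figure D2:**
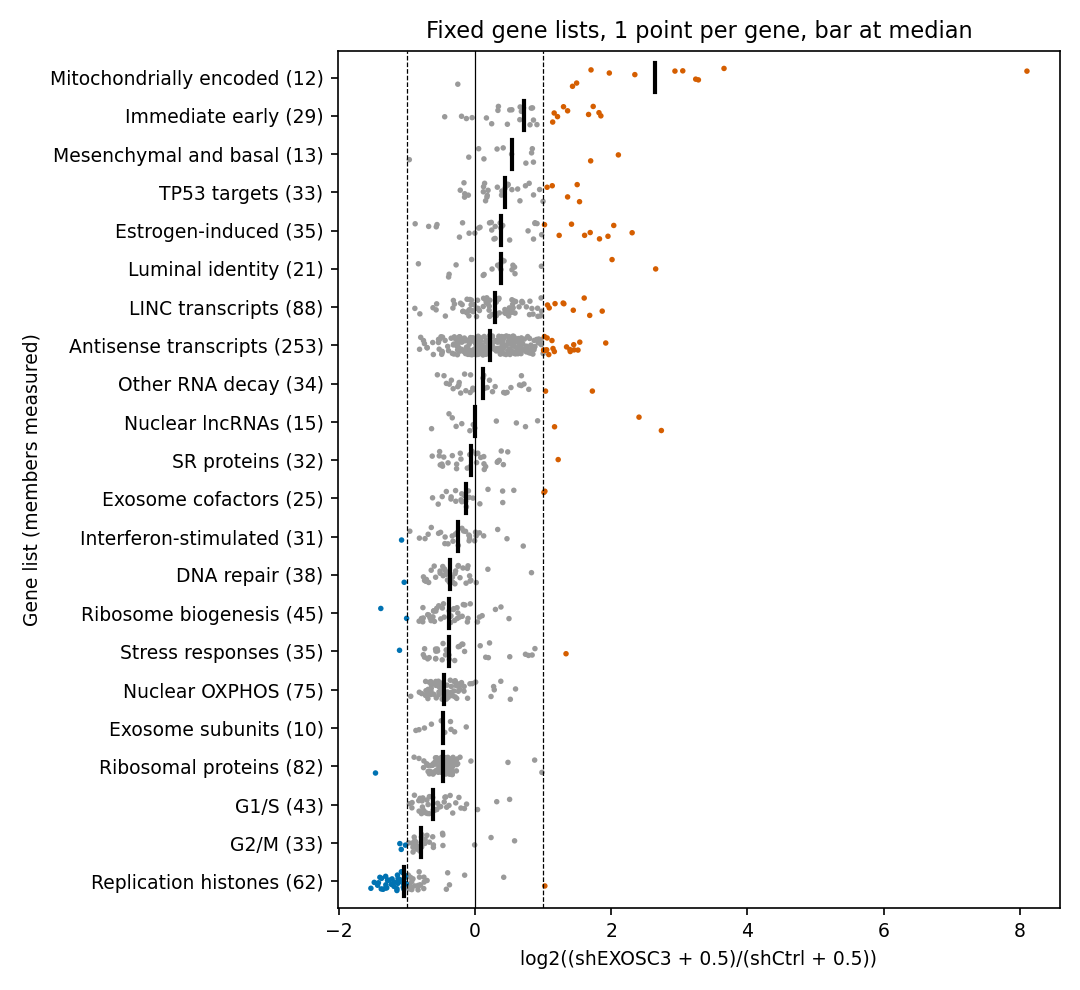
Each point is 1 gene of a fixed list, on the x axis its log2 ratio of shEXOSC3 over shCtrl (pseudocount 0.5), with the number of measured members beside each list; black bars are medians, and orange and blue points are at least 2-fold higher and lower. The medians run from 2.64 for mitochondrially encoded transcripts to -1.05 for replication-dependent histone genes. Every list but the exosome subunits has members on both sides of 0.

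SR proteins and related RNA-binding proteins stood apart by percentile, at 97.85 over 32 members, with a median of -0.06 where random lists had -0.25, with HNRNPD at 1.22 and SRSF7 at -0.63. The sign of this median depends on the scaling, with 0.07 at equal upper quartiles. The remaining lists did not stand apart or held few measured genes. Medians and percentiles were 0.00 and 32.19 for 416 zinc finger genes (ZNF703 at 2.15, ZNF385A at 2.05), -0.03 and 91.45 for cholesterol synthesis (EBP at -0.84, LSS at 0.58), -0.10 and 65.47 for glycolysis and hypoxia (EGLN3 at -0.89, P4HA2 at -0.79), and -0.07 and 36.87 for 6 NF-kB targets (LIF at 0.71, IGFBP5 at -0.67). Small RNA machinery had a median of 0.15 at percentile 90.86 (DROSHA at 0.61, TNRC6A at 0.59), and reference genes one of -0.16 at percentile 76.22 (TFRC at -0.70, PGK1 at -0.61). Of the fibroblast markers ACTA2 alone reached a mean of 1 FPKM, at 5.26 FPKM in shCtrl and 9.92 FPKM in shEXOSC3, and 0 of the leukocyte and endothelial markers did. No transcript was named as divergent in the table.

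Protein-coding genes with long transcripts were higher than those with short ones. The median log2 ratio was -0.32 in the shortest decile of 11023 genes and 0.13 in the longest, and it was -0.20 in the decile of lowest GC content and 0.08 in the highest. Without ribosomal protein, oxidative phosphorylation and histone genes the longest and shortest decile differed by 0.40, against 0.45 with them. Features of low level were also higher, with a median of 0.21 in the lowest decile by mean FPKM and -0.33 in the highest, which the random lists matched on expression take into account. Of the 21 lists that stood apart, 19 also did so with the same sign of the median once the length and GC trend was removed. The exosome subunits then lay just inside the bound, at percentile 2.51, and the SR proteins stayed past it, at 98.24, with a median of 0.02. The median was then -0.32 for ribosomal proteins, -0.28 for oxidative phosphorylation, -0.25 for the stress responses and 0.22 for the luminal list. The trend was fitted on nuclear protein-coding genes, so its removal is no check of the LINC, antisense, mitochondrial and small RNA lists. Long non-coding genes showed no such length trend, at -0.078 between the longest and the shortest quartile group. Small nucleolar RNAs, inside the bounds before, lay at percentile 100 with a median of 0.149 after this removal.

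**Figure D3:**
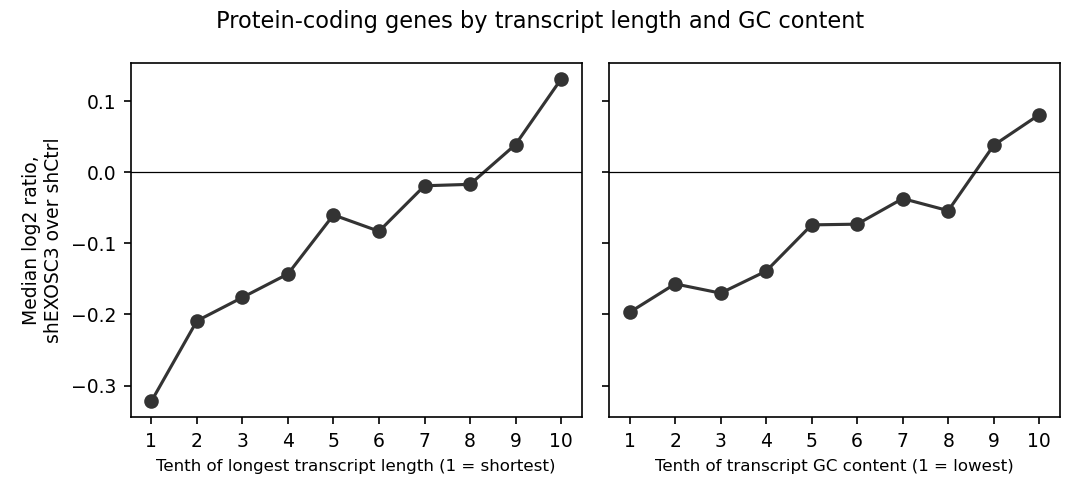
Points are medians of the log2 ratio of shEXOSC3 over shCtrl (y axis) in deciles of protein-coding genes ordered by the length of the longest transcript (left, x axis) or its GC content (right, x axis). The medians run from -0.32 to 0.13 with length and from -0.20 to 0.08 with GC content.

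In the authors' deposited table, p was under 0.05 for 679 of 20208 tested genes, 542 higher and 137 lower in shEXOSC3. The authors' deposited table gives p = 0.02495 for EXOSC3, 0.0038 for MALAT1, 0.0046 for NEAT1, 5e-05 for GATA3, 5e-05 for MT-ND4, 0.0035 for HIST1H1D and 0.00225 for CDKN1A. Of the 24 features that are the 12 highest and 12 lowest above 0 in both libraries, 20 had p under 0.05 in the authors' deposited table, which gives p = 0.11015 for MT-ATP6, 0.099 for C3orf14, 0.56635 for AC009133.22 and 0.5772 for RP11-298I3.5. That set was chosen after the values were seen. In the set fixed beforehand, 6 of the highest and 9 of the lowest features were listed at 0 in 1 library. Their p in the authors' deposited table ran from 0.0923 to 0.21135. Of the features counted here, 318 of those at least 2-fold higher and 69 of those at least 2-fold lower also had p under 0.05 in the authors' deposited table. These p-values come from a model of 2 libraries as the labels give them and compare the libraries, not the conditions.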

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

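All tests on the mitochondrial transcripts, the test of the expression trend and the bootstrap interval were chosen after the result was seen. The test of mitochondrial DNA was first the largest gain over the smallest among all 13 mRNAs, and it was restated over those with a gain because the gain of MT-ND6 was negative. Tests of ribosomal protein, oxidative phosphorylation and histone genes as the whole source of the length trend (a difference of 0.40 without them, against 0.45) and of overlapping sense genes as the source of the antisense values (a Spearman rho of 0.06 across pairs) were set beforehand; neither explanation was borne out, and they are given as values only.

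RNaseP_nuc, RPPH1 and PARP2 were flagged because they have values in shEXOSC3 but are left out of the main comparisons, as the authors' table marks them HIDATA. They stay in the sums of FPKM. RNaseP_nuc was listed at 57318.6 FPKM, RPPH1 at 1445.5 FPKM and PARP2 at 26.2 FPKM in shEXOSC3, and all of them at 0 in shCtrl. Zeros under this status are read as failed estimates, so the size of these differences is unknown. If the zeros stand for too many fragments at the locus, it would hold more fragments in shCtrl, which was not tested. RNaseP_nuc (20343075 to 20343407) lies within RPPH1 (20343048 to 20343685) on the minus strand of chromosome 14, and PARP2 (20343582 to 20357905) overlaps RPPH1 on the plus strand (hg38). Whether the same fragments give these values was not tested.

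Mitochondrially encoded mRNAs were higher in shEXOSC3, with a median log2 ratio of 2.59, and MT-RNR1 more so, at 8.11. Weaker depletion of ribosomal RNA in the shEXOSC3 library and other explanations cannot be told apart for the mRNAs or for MT-RNR1, since the median of 2.59 and the distance of MT-RNR1 above the highest mRNA, 4.21 on the log2 scale, only restate the pattern, and MT-RNR2 is a failed estimate. Carry-over of mitochondrial DNA would add about equal coverage to every gene, whereas the largest gain in FPKM was 32.7 times the smallest among the 12 mRNAs with a gain, and MT-ND6 gained -3.9 FPKM. A response to the knockdown of EXOSC3 and a difference in mitochondrial content between the cultures both stay open, untested with 1 library per group.

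Long protein-coding genes were higher and short ones lower, by 0.45 between the longest and the shortest decile. Low expression is not the whole cause, since the difference was 0.451 at a mean of at least 5 FPKM. The trend of the log2 ratio with expression level removes part of it and leaves 0.322. A bias of the libraries with length would be shared by long non-coding genes, but their longest quartile group lay -0.078 from the shortest (95% bootstrap interval -0.175 to 0.025), against 0.311 in protein-coding genes. Their annotated lengths are less complete and their length range differs. The LINC and antisense lists had median lengths of 1954 and 2056 bp, within the protein-coding decile from 1616 to 2161 bp. The interval carries no error between libraries. A length bias is therefore not excluded, and the knockdown itself stays open as a hypothesis that 1 library per group does not test.

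Replication-dependent histone mRNAs were lower by a median log2 ratio of -1.05. The trend with length and GC content leaves a median of -0.80 and so does not account for it. A smaller share of cells in S phase in the shEXOSC3 culture is a candidate explanation, since G1/S genes lay at percentile 0.0 of random lists with the trend removed. G2/M genes lay there too, with a median of -0.637 against -0.483 for G1/S genes, so these values are not specific to S phase. The data hold no count of cells by phase, so a direct effect of the knockdown on histone mRNA stays open.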

How the results depend on the processing

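The authors' p under 0.05, the removed length and GC trend, and the settings with failed estimates kept, features listed at 0 left out or mitochondrial genes left out were chosen after seeing the data. The log2 ratio of EXOSC3 lay between -3.19 and -2.89 in 14 alternatives. Against 628 features at least 2-fold higher, there were 319 at a mean of at least 5 FPKM, where only 9467 features are counted, and 336 by the authors' p. Against 155 lower, there were 98 at equal upper quartiles and 76 by the authors' p. For the counts by the authors' p the cause was not tested. The other counts stayed within 1.5 times, 13 in each direction. Equal upper quartiles multiply the shEXOSC3 values by a factor of 0.127 on the log2 scale, and the share of higher among 2-fold features was then 89.5%, against 80.2%. That share was 73.2% at equal sums and 74.2% at a mean of at least 5 FPKM. Among the lists that stood apart, 271 alternative medians stayed within 1.5 times of the log2 value, 19 did not and 2 changed sign. With no filter on low values the median was 0.038 for LINC, 0.086 for antisense and 0.115 for mesenchymal and basal genes, each over more members. At a mean of at least 5 FPKM it was 0.047 for other RNA decay, 0.122 for antisense and -0.09 for interferon-stimulated genes, over fewer members. SR proteins were at -0.012 when median-centred, -0.124 at equal sums, 0.065 at equal upper quartiles and 0.022 with the trend removed, against -0.06. Other RNA decay was at 0.06 at equal sums. The sums behind this scaling include RNaseP_nuc, a failed estimate listed at 57318.6 FPKM in shEXOSC3 and at 0 in shCtrl. Equal upper quartiles gave 0.241 for other RNA decay, 0.327 for antisense, -0.135 for interferon-stimulated and -0.241 for DNA repair genes. Protein-coding genes alone left 6 antisense members at 0.053. The removed trend gave 0.36 for antisense, -0.318 for ribosomal proteins, 0.218 for luminal, -0.245 for stress and -0.283 for oxidative phosphorylation genes. It was fitted on nuclear protein-coding genes, so its values for non-coding lists are no check. Beyond the settings' own construction, the cause was not tested. Among the 12 lists that did not stand apart, 118 of 162 alternative medians stayed within 1.5 times of the log2 value, 28 did not and 16, in 8 lists, changed sign. With the trend removed, snoRNA hosts were at 0.03 against -0.145 and small RNA machinery at -0.052 against 0.151, and with no filter microRNA hosts were at 0.141 against 0.369. For the 24 named genes the bound was 1.5 times in fold, and BCL9L alone passed it, at a log2 ratio of 2.334 with the trend removed. The authors' q values were not run because the table has no such column, and no library could be left out with 1 per group. No paired analysis was possible because each group has 1 library. Depth limits genes near 1 FPKM, where counting error is about ±15% at 2 kb and features under 300 bp rest on fewer fragments.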

Other observations

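By annotated class, chosen after the data were seen, intergenic long non-coding RNAs had a median log2 ratio of 0.41 at percentile 100 of random lists matched on expression, with 45 of 424 features at least 2-fold higher and 0 lower. Annotated antisense genes had a median of 0.32 at percentile 100, with 55 of 524 at least 2-fold higher and 1 lower. The percentiles rank medians, and these counts past 2-fold were not ranked against random lists. Bidirectional promoter transcripts, which start next to a gene and run away from it, had a median of 0.51 at percentile 97.67 over 13 features. Processed pseudogenes, copies of spliced mRNAs, had a median of -0.20 at percentile 0 over 250 features, where random lists had 0.15. Whether their values come from reads of the mRNAs they copy was not tested. Sense intronic transcripts, at 0.22 and percentile 78.53 over 93 features, and transcribed unprocessed pseudogenes, at 0.05 and percentile 10.06 over 145, did not stand apart.

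Protein-coding genes in the top quartile of both length and GC content had a median log2 ratio of 0.44 over 318 genes, and those in the bottom quartile of both had -0.34 over 324. Across genes the log2 ratio had a Spearman rho of 0.25 with length and 0.17 with GC content, over 11023 genes that are not independent replicates.

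Failed estimates outside the comparisons included EXOSC9, at 37.5 FPKM in shCtrl and 25.9 FPKM in shEXOSC3, and the cyclin CCNA2, at 81.8 and 36.6 FPKM. MT-RNR2, the large mitochondrial ribosomal RNA, was listed at 131 FPKM in shCtrl and at 0 in shEXOSC3 under the status HIDATA. Its log2 ratio is therefore unknown. If the 0 stands for too many fragments, as the status means, MT-RNR2 would be higher in shEXOSC3, which was not tested.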
